A study of Mus musculus with 6 samples.

How the data were processed

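The series compared testes of mice at postnatal day 14 by RNA sequencing. Per the labels, 3 samples were wild type (WT) and 3 carried the genotype called sKO, which the series title describes as a conditional deletion of Rif1 in germ cells before they enter meiosis. The labels give no litter, batch or date. Per the labels' protocols, messenger RNA was captured from total RNA with oligo-dT magnetic beads.

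The deposited values were raw read counts per gene symbol, in 1 table for the whole series with 1 column per sample. Per the submitters' processing notes, the tools used were Trim Galore, HISAT2 and featureCounts, and the genome build was mm39. Tool versions, the annotation release, the strand setting and the treatment of reads that match several places are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical paralogs can therefore not be told apart in these counts. The columns carried the group words con and scKO, which were read as WT and sKO, and were matched to the samples by replicate number. The table held 50763 gene symbols, of which 15678 had a count of 0 in all 6 libraries.

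Total counts per library ranged from 15941672 to 18296594, so 3 counts correspond to 0.164 to 0.188 CPM (counts scaled to a common library total in the usual way), the limit that a count of 0 allows. Such limits cover counting error alone, because reads without molecular identifiers are not independent molecules. Within each group every pair of libraries differed by more than counting noise (chi-square per degree of freedom 4.81 to 22.7), so none was a repeat count of the same library. That spread does not show that the samples were separate; the 6 were used as replicates because the labels list them as separate samples.

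Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, libraries were scaled with TMM factors, and sKO was tested against WT with the robust quasi-likelihood F test without covariates. P-values were adjusted by the Benjamini-Hochberg method over the 18860 genes tested, and genes with an adjusted p under 0.05 are referred to as called. CPM values use the TMM-scaled library sizes. The standard error (SE) of a log2 fold change was derived from its F statistic. The SE of a list median was taken over the list's genes as if they were independent, so it leaves out the spread between samples. Gene lists and chromosomes were tested with camera (limma 3.58.1) at an inter-gene correlation of 0.01, with adjustment over the 27 lists or over the chromosomes. Each list was tested again with camera at an estimated correlation and with fry. Members called after adjustment within a list are described as adjusted over the list alone.

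The 27 lists, the tests of genes, lists and chromosomes, and the alternatives were fixed before the data were examined, except for the additions and tests of explanations that are named as chosen later. The lists covered germ cell stages, the machinery of meiotic prophase, other testis cell types and neighbouring tissues, DNA replication and repair, and stress, interferon and metabolic responses. They held 565 entries, of which 552 were found in the table, 1 of them through a synonym. For the mitochondrial list the 13 protein-coding genes of the mitochondrial chromosome were used. The rule for naming genes was also fixed then. It took Rif1, up to 12 of the largest rises and 12 of the largest falls among called genes with a mean of at least 1 CPM, non-overlapping groups and a symbol other than a predicted name, and the members with the smallest p of each list (up to 4 for a list past the threshold or with 3 or more called members, up to 3 for the others). The rule gave 114 gene entries, of which the text names a part, and 1 result that it covers is not reported. Genes outside the rule are marked as chosen after their values were seen. A further 4 lists (axonemal families, interferon-inducible GTPases, antigen presentation and a second epididymis list) were also defined after the data were seen.

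Chromosomes were assigned by symbol or synonym from a RefSeq gene table of assembly GRCm38, which matched 46277 of the symbols (91.2%). Because the counts were made on mm39, no coordinates are given. Transcript GC content came from a GENCODE annotation of GRCm38 and was available for 89.2% of the tested genes.

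The scripts were tested on simulated data for the sKO against WT comparison, with counts drawn from the means and library sizes of these samples. With 18543 genes tested, edgeR recovered 66 of 100 genes changed by 1 log2 unit. It recovered 95 of 100 changed by 2 log2 units, with 14 false calls. DESeq2 and limma-voom recovered 69 and 68 of 100 at 1 log2 unit, with 27 and 9 false calls. On the samples themselves edgeR, DESeq2 and limma-voom called 246, 777 and 15 genes, a spread that the simulated data did not show. These recovery rates therefore may not hold for the samples. In a simulation with 18504 genes tested, camera found the shifted list and called 0 of 20 unshifted lists. The lists were random and genes were drawn independently. The simulation therefore does not test camera on lists whose genes move together, such as the pachytene list (estimated correlation 0.51).

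The alternatives were DESeq2 1.42.0 and limma-voom in place of edgeR, RLE factors or library size alone in place of TMM, no filter beyond 1 count in any library, a filter of at least 1 CPM in 3 libraries, the replicate number as a block, and leaving out each library in turn. An offset for GC content and a fit without both libraries numbered 1 were added after the data were seen. All 10 ways to split the 6 libraries into groups of 3 were also fitted. Analyses used Python 3.11.15 with pandas 2.3.3 for reading the table and matplotlib 3.10.9 for the plots. Transposable elements, splicing and the deleted exons were not analysed here, because the counts are per gene.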

Results

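Testis transcriptomes at postnatal day 14 were compared between wild-type mice (WT) and mice lacking Rif1 in germ cells from before meiosis (labelled sKO). RIF1 acts with 53BP1 at DNA double-strand breaks and controls the timing of DNA replication. At this age the first wave of spermatogenesis has brought germ cells into meiotic prophase, and spermatids are largely missing. Poly(A) RNA of 3 WT and 3 sKO testis samples was sequenced. Total counts were 18156109, 16665816 and 15941672 in WT libraries 1 to 3 and 16819064, 16605787 and 18296594 in sKO libraries 1 to 3. The most abundant gene, mitochondrial COX1, took between 0.961% and 1.49% of the counts of a library. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may be technical.

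The groups separated on the first principal component, which held 53.1% of the variance. WT libraries 1 to 3 had scores of -56.3, -21.6 and -12.4 and sKO libraries 1 to 3 had scores of 51.7, 35.3 and 3.18. WT library 1 and sKO library 3 thus lay farthest from the others of their group in opposite ways, the first away from sKO and the second towards WT.

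The targeted gene, Rif1 on chromosome 2 (RefSeq, GRCm38), was examined first. Its level was 103 ± 23.3 CPM in WT (SD, n = 3) and 45.8 ± 3.62 CPM in sKO (SD, n = 3). The WT libraries held 96.5, 83.7 and 129 CPM, and the sKO libraries held 42.0, 46.4 and 49.2 CPM. Rif1 fell by 1.17 on the log2 scale (SE 0.15, edgeR adjusted p = 0.0145), a level 2.25-fold lower in sKO. An exact two-sided permutation test of the 3 WT against the 3 sKO libraries gave p = 0.1, the smallest that this design allows. The edgeR adjusted p was 0.137 without WT library 2, 0.0618 without sKO library 1 and 0.120 without sKO library 2, with log2 fold changes of -1.30, -1.13 and -1.17. The counts cover the whole gene and all cells of the testis, and the deleted exons are not given in the sources used here.

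The comparison of sKO with WT asked which transcripts of the juvenile testis differ when germ cells lack Rif1. Of 18860 genes tested with edgeR, 240 were lower and 6 were higher, and 182 and 3 of these differed by at least 2-fold. Groups did not overlap for 20.2% of tested genes, where chance gives 10% on average. Genes move together and the share was not computed for other splits of the libraries, so the excess was not tested. Among the genes without overlap the directions were closer in number. Of them, 2009 were lower in every sKO library than in every WT library, and 1806 were higher. The called lower genes had a median log2 fold change of -1.83 and a median WT level of 9.82 CPM, and 69 of the 240 carried predicted names.

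The 12 largest falls that the naming rule covers had log2 fold changes from -4.70 to -3.50. Zmynd10, an assembly factor of axonemal dyneins, fell from 24.6 ± 12.02 to 1.99 ± 0.960 CPM (SD, n = 3 each; log2 fold change -3.61, SE 0.47, edgeR adjusted p = 0.0251). Qrich2, a protein of the sperm flagellum, fell by 3.73 on the log2 scale (SE 0.44, edgeR adjusted p = 0.0145), and Catsperb, a subunit of the sperm calcium channel CatSper, fell by 3.81 (SE 0.71, edgeR adjusted p = 0.0352). Fbp1, the gluconeogenic fructose bisphosphatase, fell by 4.39 (SE 0.70, edgeR adjusted p = 0.0325). Fam181a had log2 fold change -4.70, Lrrc37a -4.51, Plaat5 -4.17, Potefam1 -3.89, Pabpc2 -3.83, Rbakdn -3.77, Mir7232 -3.50 and Abcc12 -3.50. Most of these 12 transcripts were at a low level, with 37 to 136 counts of Fam181a per WT library and 2 to 5 per sKO library. Lrrc37a, Potefam1 and Pabpc2 belong to families of similar genes and Mir7232 and Rbakdn can share reads with neighbouring genes, so their counts are uncertain.

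The 6 genes called higher changed less. Gzmc, a granzyme with close paralogs, rose by 1.35 on the log2 scale (SE 0.27, edgeR adjusted p = 0.0440). The interferon-induced genes Ifit3 and Iigp1 rose by 1.32 (SE 0.27, edgeR adjusted p = 0.0440) and 1.27 (SE 0.26, edgeR adjusted p = 0.0475). Padi2, a peptidylarginine deiminase, rose from 55.6 ± 7.45 to 83.6 ± 5.99 CPM (SD, n = 3 each). Btg2, an antiproliferative p53 target, rose from 35.3 ± 0.352 to 52.5 ± 4.32 CPM, and Sel1l3 rose from 36.1 ± 3.93 to 52.7 ± 1.76 CPM (SD, n = 3 each).

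The count of lower genes depended on single libraries. It was 101, 0 and 502 without WT library 1, 2 or 3 and 0, 0 and 624 without sKO library 1, 2 or 3, and where edgeR called 0 genes in either direction, 1662, 1410 and 1221 genes were lower at an unadjusted p under 0.05, against 1611 with all libraries, and 1102, 431 and 503 were higher, against 954. In those 3 fits 0 of the genes named here were therefore called. DESeq2 called 721 genes lower and 56 higher, limma-voom called 15 and 0, and a fit without both libraries numbered 1, added after the data were seen, called 155 and 5.

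**Figure D1:**
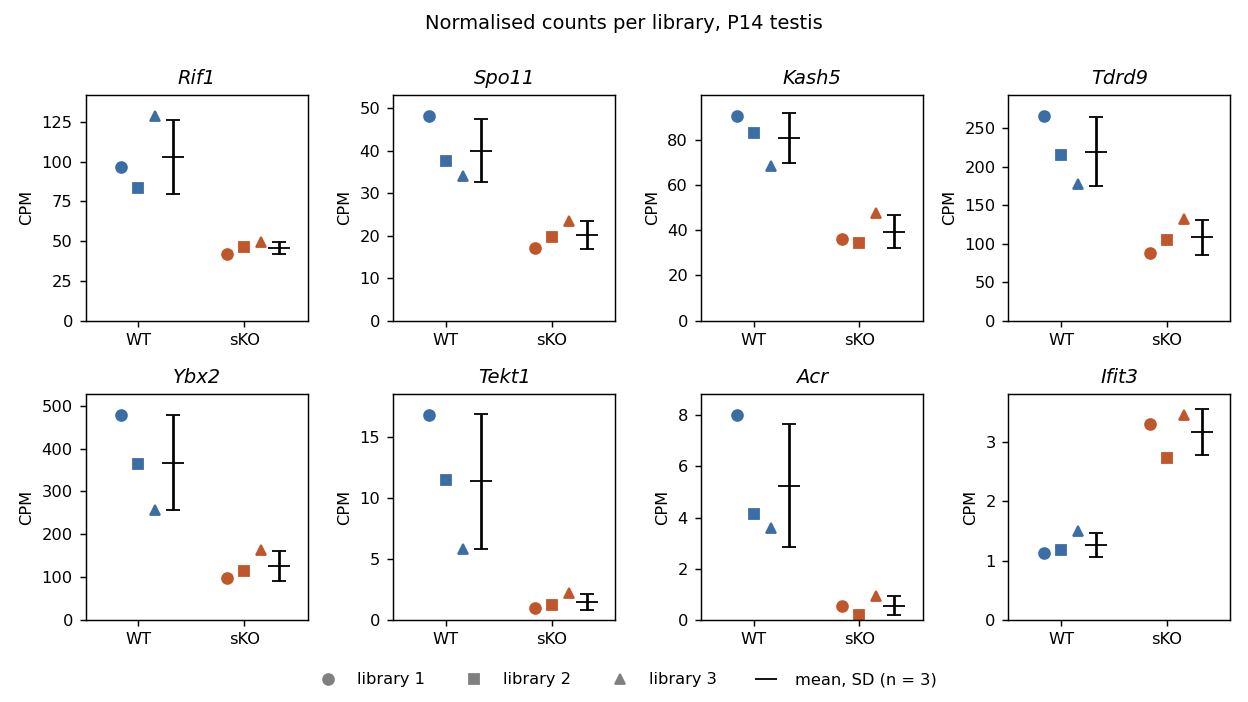
Normalised counts (CPM, linear axes from 0) of 8 genes in each of the 3 WT and 3 sKO libraries, with the mean and SD of each group beside the points. Rif1, Spo11, Kash5, Tdrd9, Ybx2, Tekt1 and Acr lie lower in every sKO library than in every WT library, and Ifit3 lies higher.

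Among the germ cell lists, genes of pachytene spermatocytes differed most. Of 26 tested members, 25 had lower estimates in sKO and the median log2 fold change was -1.29. edgeR called 4 lower and 0 higher over all genes, and 19 were lower when adjusted over the list alone, while DESeq2 called 16 lower and limma-voom 0. Acr, the protease proacrosin, fell by 3.22 on the log2 scale (SE 0.48, edgeR adjusted p = 0.0243), from 5.25 ± 2.41 to 0.552 ± 0.377 CPM (SD, n = 3 each). The microtubule protein Tekt1 fell by 2.95 (SE 0.43, edgeR adjusted p = 0.0245), and the cilia-associated Nme5 fell by 1.58 (SE 0.33, edgeR adjusted p = 0.0480). Ybx2, a germ cell RNA-binding protein, fell from 367 ± 111 to 126 ± 34.1 CPM (SD, n = 3 each; log2 fold change -1.55, SE 0.27, edgeR adjusted p = 0.0490). The camera test, which is two-sided, gave adjusted p = 2.29e-22 for the list, and adjusted p = 0.426 with an estimated correlation.

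Other abundant members of that list, chosen after their values were seen, had large estimates that did not pass the test over all genes. Ldhc, the germ cell lactate dehydrogenase, stood at 76.9 ± 46.6 CPM in WT and 4.27 ± 2.21 CPM in sKO (SD, n = 3 each; edgeR adjusted p = 0.0657). Piwil1, a piRNA-binding protein, stood at 120 ± 70.2 CPM in WT and 10.9 ± 6.21 CPM in sKO (SD, n = 3 each; edgeR adjusted p = 0.0933). An exact two-sided permutation test gave p = 0.1 for each, the smallest possible. The WT libraries themselves differed: the list's median level relative to the WT mean was 0.54, -0.12 and -0.45 (log2) in WT libraries 1 to 3 and -1.28, -1.28 and -0.84 in sKO libraries 1 to 3. Leaving out each library in turn gave list medians between -1.62 and -0.98.

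Genes that act earlier in meiotic prophase differed less. In the meiotic recombination list 2 of 32 members were called lower and 15 were lower when adjusted over the list alone, with a median log2 fold change of -0.40; DESeq2 called 10 lower and limma-voom 0. Spo11, which makes the double-strand breaks, fell from 39.9 ± 7.40 to 20.1 ± 3.20 CPM (SD, n = 3 each; log2 fold change -0.99, SE 0.16, edgeR adjusted p = 0.0253). Psmc3ip, an accessory factor of the recombinases, fell by 0.89 on the log2 scale (SE 0.18, edgeR adjusted p = 0.0436). Hsf2bp and Rnf212b had log2 fold changes of -0.58 and -0.65 with edgeR adjusted p of 0.0568 and 0.0596. In the list of the chromosome axis and synaptonemal complex 2 of 23 members were called lower and 9 were lower when adjusted over the list alone, with a median of -0.34, while DESeq2 called 4 lower and limma-voom 1. Kash5 and Majin, which tie meiotic telomeres to the nuclear envelope and its motors, fell by 1.04 (SE 0.15, edgeR adjusted p = 0.0178) and 0.72 (SE 0.15, edgeR adjusted p = 0.0480). For recombination camera gave adjusted p = 7.31e-12 and for the axis list 5.75e-07, and with an estimated correlation adjusted p = 0.426 and 0.446.

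The piRNA pathway list, whose products silence transposons in germ cells, had 4 of 22 members called lower and 13 lower when adjusted over the list alone, with a median of -0.47 (-0.31 without WT library 1). DESeq2 called 9 lower and limma-voom 0. The helicases Tdrd9 and Mov10l1 fell by 1.02 (SE 0.18, edgeR adjusted p = 0.0314) and 0.71 (SE 0.13, edgeR adjusted p = 0.0314). Piwil2, a piRNA-binding protein, fell from 387 ± 84.2 to 225 ± 28.0 CPM (SD, n = 3 each; edgeR adjusted p = 0.0417), and Gtsf1 fell from 30.8 ± 4.22 to 19.9 ± 0.795 CPM (SD, n = 3 each; edgeR adjusted p = 0.0480). The piRNA list had a camera adjusted p = 5.13e-13, and adjusted p = 0.426 with an estimated correlation. Of 28 spermatid genes 11 were expressed enough to be tested, 2 were called lower and 3 were lower when adjusted over the list alone, against 3 with DESeq2 and 0 with limma-voom. The 2 were Tex101, a germ cell surface protein, which fell by 0.75 (SE 0.12, edgeR adjusted p = 0.0245), and the actin-like Actl7b, which fell by 3.40 (SE 0.66, edgeR adjusted p = 0.0417), while Crisp2 had a log2 fold change of -3.76 at an edgeR adjusted p of 0.0665. The spermatid list had a median of -0.33 (-0.59 without WT library 1), with camera adjusted p = 8.39e-05, and adjusted p = 0.310 with an estimated correlation.

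Markers of spermatogonia showed no such fall. Of 21 undifferentiated and 13 differentiating spermatogonia genes edgeR called 0, over all genes or when adjusted over the list alone, and at an unadjusted p under 0.05 there were 2 higher and 1 lower in the first list and 1 higher and 1 lower in the second. DESeq2 called 1 lower in the first list and 0 in the second, and limma-voom called 0 in both. Their median log2 fold changes were 0.18 (camera adjusted p = 0.0639) and 0.09 (camera adjusted p = 0.224). The median of the differentiating list lay between 0.04 and 0.16 when each library was left out. Ret, the receptor for GDNF signalling in stem spermatogonia, had a log2 fold change of 0.30, and Id4 had one of -0.69 with an edgeR adjusted p of 0.200. The undifferentiated list passed the threshold without WT library 2 (median 0.24, camera adjusted p = 0.0288), without the low-count filter (0.16, 0.0462) and with limma-voom (0.16, 0.0437), but not with an estimated correlation (adjusted p = 0.426), and its median was 0.0789 without sKO library 3.

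**Figure D2:**
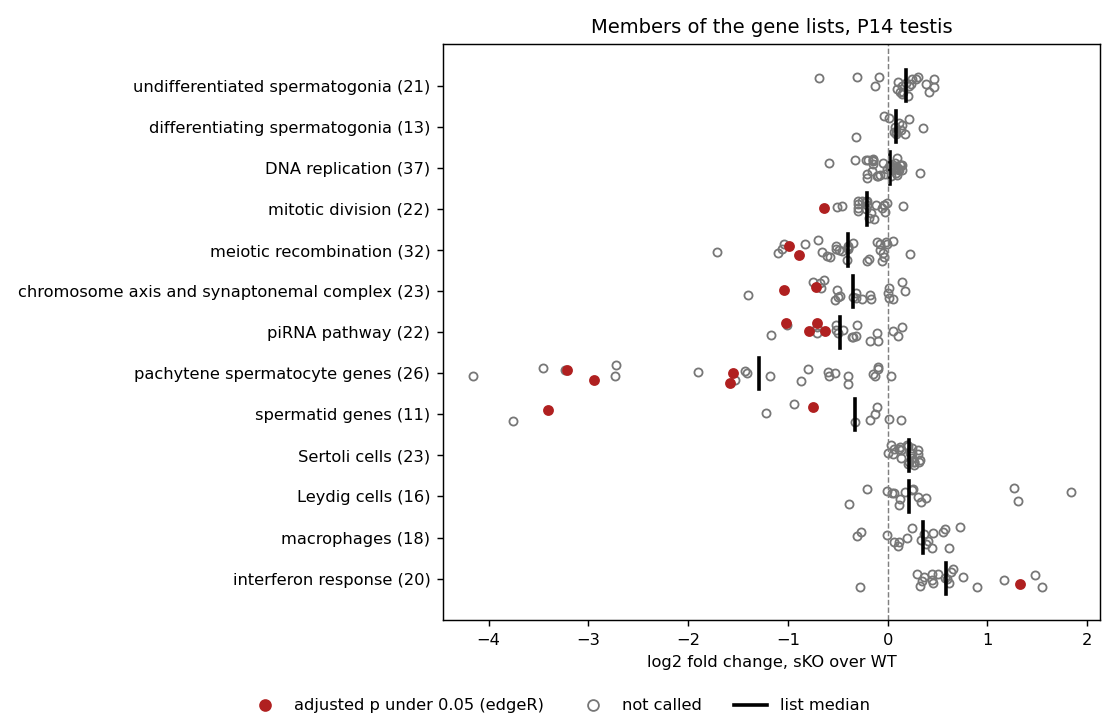
Log2 fold change of sKO over WT (edgeR) for every tested member of 13 gene lists, with the number of tested members in brackets, filled points for genes with an adjusted p under 0.05 and a bar at each list's median. The pachytene list has the lowest median (-1.29), the spermatogonia lists have medians of 0.18 and 0.09, and the interferon list has a median of 0.59.

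Genes of cell division and DNA repair were next. In the mitotic division list 1 of 22 members was called lower, 2 were lower when adjusted over the list alone, and 21 had lower estimates, with a median log2 fold change of -0.21. DESeq2 called 2 lower and limma-voom 0. Cdc20, an activator of the anaphase-promoting complex, fell from 151 ± 19.9 to 97.2 ± 8.59 CPM (SD, n = 3 each; edgeR adjusted p = 0.0314), and the cyclin Ccnb2 had a log2 fold change of -0.51 at an edgeR adjusted p of 0.0510. For mitotic division camera gave adjusted p = 4.66e-05, and adjusted p = 0.426 with an estimated correlation. The DNA replication list (37 genes) had a median of 0.03 while camera pointed lower (adjusted p = 0.550). Its median lay between -0.05 and 0.02 when each library was left out. Gins1 had a log2 fold change of -0.59 with an edgeR adjusted p of 0.110.

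The 53BP1 pathway, in which RIF1 itself acts, had 0 of 23 members called by edgeR, 2 lower when adjusted over the list alone and 3 lower at an unadjusted p under 0.05, while DESeq2 called 2 lower and limma-voom 0. Those 2 were Mad2l2, a shieldin subunit, and the DNA damage mediator Mdc1, with log2 fold changes of -0.60 and -0.60 and edgeR adjusted p of 0.0782 and 0.0807. The list's median was -0.03 (camera adjusted p = 0.424), and lay between -0.10 and 0.06 when each library was left out. Homologous recombination and checkpoint genes had a median of -0.09 over 34 members with 0 called by edgeR over all genes or adjusted over the list alone, and 5 lower at an unadjusted p under 0.05; DESeq2 called 2 lower and limma-voom 0. The list had a camera adjusted p = 0.0277, and adjusted p = 0.500 with an estimated correlation. Among them were Rad9b (log2 fold change -0.50, edgeR adjusted p = 0.0751) and the kinase Atr (log2 fold change -0.52, edgeR adjusted p = 0.123). This list lost its call without WT library 1 (median -0.04, camera adjusted p = 0.189), WT library 3 (-0.10, 0.0540), sKO library 1 (-0.10, 0.0716) or sKO library 2 (-0.05, 0.148), and had a median of -0.17 without sKO library 3 (0.00217).

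Somatic cell markers had slightly higher estimates in sKO. All 23 Sertoli cell markers had higher estimates, with a median log2 fold change of 0.21, though edgeR called 0 of them over all genes or adjusted over the list alone and 8 were higher at an unadjusted p under 0.05; DESeq2 and limma-voom also called 0. Wt1 stood at 226 ± 3.37 CPM in WT and 272 ± 14.8 CPM in sKO (SD, n = 3 each; edgeR adjusted p = 0.181), and Sox9 at 110 ± 2.05 and 132 ± 12.9 CPM (SD, n = 3 each; edgeR adjusted p = 0.243). Camera gave adjusted p = 6.38e-05 for Sertoli cells, and adjusted p = 0.426 with an estimated correlation. Median log2 fold changes were 0.21 for 16 Leydig cell markers, 0.29 for 10 peritubular myoid markers and 0.35 for 18 macrophage markers, with 0 members called by edgeR over all genes or adjusted over the list alone and 2, 0 and 2 higher at an unadjusted p under 0.05. DESeq2 and limma-voom also called 0 members of these 3 lists. Cyp17a1, a steroidogenic enzyme of Leydig cells, varied from 189 to 444 counts in WT and from 427 to 1368 in sKO. Camera gave adjusted p = 0.0304, 0.00870 and 0.0260 for these 3 lists, and with an estimated correlation adjusted p = 0.456, 0.500 and 0.456.

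Calls for those 3 lists rested on single libraries. The Leydig list had a median of 0.13 without WT library 1 (camera adjusted p = 0.3004) and 0.12 without sKO library 1 (0.191), the myoid list 0.20 (0.0997) and 0.05 (0.373), and the macrophage list 0.08 without WT library 1 (0.209) and, still past the threshold, 0.23 without sKO library 1 (0.0481). Endothelial markers (median 0.18, camera adjusted p = 0.280), interstitial stroma (0.07, 0.430), red blood cell genes (-0.29, 0.424) and adipose genes (-0.34, 0.596) did not pass the test with all libraries. Stroma passed without sKO library 3 (0.23, camera adjusted p = 0.00381). Adipose genes passed without WT library 1 (-0.74, camera adjusted p = 0.0254) and without both libraries numbered 1 (-1.50, 5.59e-08), a fit added after the data were seen. The adipose list was highest in WT library 2, at 1.42 (log2) relative to the WT mean. It stood at -1.94 and 0.47 in WT libraries 1 and 3 and at 0.68, -0.26 and -0.89 in sKO libraries 1 to 3.

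One sKO library also held transcripts of the epididymis, the duct next to the testis. Crisp1, an epididymal secretory protein, reached 89.7 CPM in sKO library 1 against 10.7 CPM in WT library 2, 5.39 CPM in sKO library 2 and 2.55 CPM or less in the other 3. Cdh16 and Adam7 stood at 43.7 and 13.2 CPM in sKO library 1, against at most 4.48 and 2.06 CPM elsewhere; Crisp1 and Cdh16 were chosen after their values were seen. The epididymis and rete list had a median log2 fold change of 1.99 (camera adjusted p = 0.0353), and adjusted p = 0.529 with an estimated correlation, with 0 of 9 members called by edgeR, DESeq2 or limma-voom and 1 higher at an unadjusted p under 0.05. Without sKO library 1 its median was 0.000657 (camera adjusted p = 0.587), and it also lost its call without WT library 1 (1.61, 0.221) or WT library 3 (1.70, 0.0540). The myoid and Leydig lists, too, were highest in sKO library 1, at 0.62 and 0.43 (log2) relative to the WT mean.

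Interferon response genes were higher in sKO. Of 20 tested members 19 had higher estimates, 1 was called by edgeR over all genes and 11 were higher when adjusted over the list alone, with a median log2 fold change of 0.59. DESeq2 called 3 higher and limma-voom 0. Ifit3 stood at 1.26 ± 0.200 CPM in WT and 3.16 ± 0.389 CPM in sKO (SD, n = 3 each). The antiviral genes Oas2 and Rigi had log2 fold changes of 1.17 and 0.61 with edgeR adjusted p of 0.0901 and 0.119. Relative to the WT mean, the list stood at -0.18, 0.03 and 0.15 in WT libraries 1 to 3 and at 0.68, 0.39 and 0.65 in sKO libraries 1 to 3. Camera gave adjusted p = 1.70e-09, and adjusted p = 0.426 with an estimated correlation. Most members were expressed at a few CPM.

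**Figure D3:**
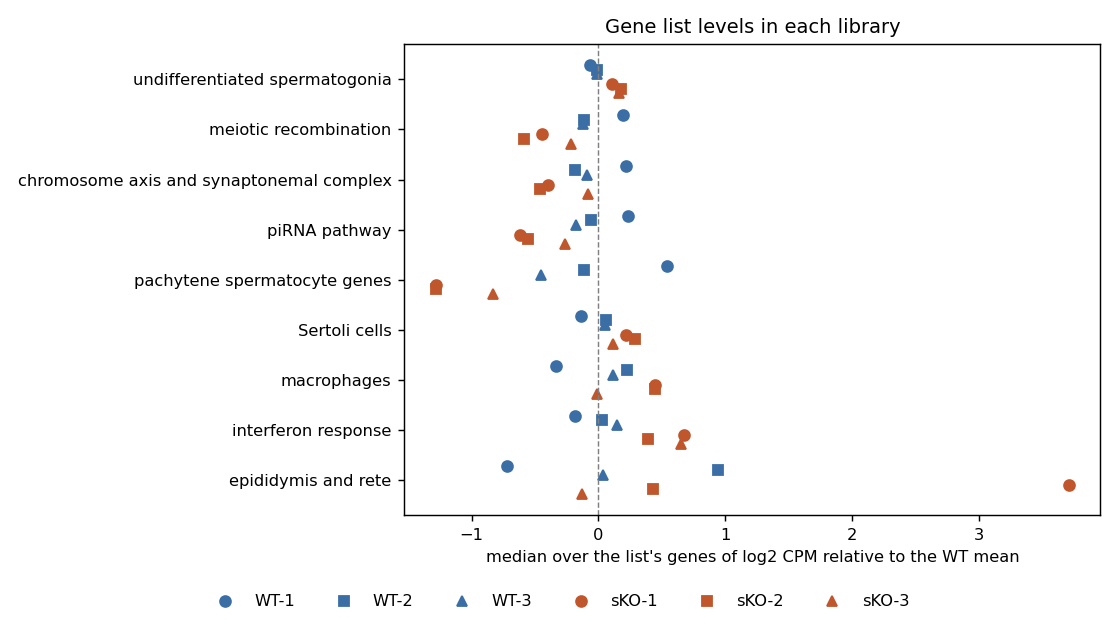
Level of 9 gene lists in each library, as the median over a list's genes of log2 CPM relative to the WT mean, with blue symbols for WT and orange symbols for sKO libraries. The pachytene list lies between -0.45 and 0.54 in WT and between -1.28 and -0.84 in sKO, and the epididymis list lies at 3.71 in sKO library 1.

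The other stress and metabolic lists and the chromatin repressors had median log2 fold changes from -0.03 to 0.27. The p53 targets had a median of 0.09 over 24 genes with Btg2 as the 1 called member, also the 1 when adjusted over the list alone (camera adjusted p = 0.0453), and adjusted p = 0.456 with an estimated correlation. Within it, Ccng1 had a log2 fold change of 0.35 and Mdm2 one of -0.24. Immediate early genes had a median of 0.27 over 17 genes (camera adjusted p = 0.0353), and adjusted p = 0.456 with an estimated correlation; Atf3 and Jun had log2 fold changes of 0.70 and 0.37 with edgeR adjusted p of 0.174 and 0.180. The 13 mitochondrial genes had a median of 0.16 (camera adjusted p = 0.0496), and adjusted p = 0.456 with an estimated correlation. These 3 lists lost their calls, respectively, without WT library 2 or 3 or sKO library 1 or 3 (medians 0.13, 0.11, 0.05 and 0.09, camera adjusted p 0.188, 0.0540, 0.197 and 0.0832), without WT library 1 or 3 or sKO library 2 or 3 (0.13, 0.23, 0.20 and 0.15, adjusted p 0.155, 0.110, 0.0566 and 0.0832), and without WT library 2 or sKO library 3 (0.04 and 0.02, adjusted p 0.562 and 0.127). The mitochondrial median was 0.29 without WT library 1 (camera adjusted p = 0.00148). The p53 and mitochondrial lists also lost their calls with the filter of at least 1 CPM in 3 libraries (camera adjusted p = 0.0518 and 0.0529). Cholesterol synthesis genes (median 0.11, camera adjusted p = 0.0560) and chromatin repressors (-0.03, 0.672) did not pass. The cholesterol list passed without WT library 3 (0.19, camera adjusted p = 0.0230) or sKO library 2 (0.12, 0.0384), without the low-count filter (0.10, 0.0194) and with limma-voom (0.12, 0.0437).

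Genes of the 2-cell embryo are repressed in most tissues. The 21 listed genes found in the table held 82, 59 and 69 counts in WT libraries 1 to 3 and 119, 80 and 101 counts in sKO libraries 1 to 3. The 3 genes with enough counts to be tested gave 73, 44 and 57 of the WT counts and 107, 71 and 86 of the sKO counts. The 6 Zscan4 genes, none of which was tested, together had 0, 0 and 1 counts in WT libraries 1 to 3 and 1, 0 and 3 counts in sKO libraries 1 to 3, where a count of 0 allows up to 0.164 to 0.188 CPM. The 3 tested of 25 fixed genes had a median log2 fold change of 0.57 (camera adjusted p = 0.206), among them Sp110, also an interferon-induced gene, with an edgeR adjusted p of 0.3296. When each library was left out, the list's median lay between -0.21 and 0.69.

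X-linked genes as a set were slightly higher in sKO. The median log2 fold change over 741 X-linked genes was 0.15, against 0.03 over all genes, and 606 of them had higher estimates, with 0 called by edgeR and 72 higher and 1 lower at an unadjusted p under 0.05. DESeq2 called 2 of them higher and limma-voom 0. X-linked genes took 3.13%, 3.09% and 3.38% of counts in WT libraries 1 to 3 and 3.64%, 3.54% and 3.46% in sKO libraries 1 to 3. Camera gave adjusted p = 1.16e-06 over the chromosomes, and adjusted p = 0.912 with an estimated correlation. Chromosome 2, which carries Rif1, had a median of 0.02 over 1424 genes (camera adjusted p = 0.913), with 12 called lower.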

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

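The GC offset and the fit without both libraries numbered 1 were chosen after the results were seen, and the other alternatives before. Under all 15 alternatives Rif1 kept its direction; it lost its call without WT library 2, sKO library 1 or sKO library 2, and its log2 fold change lay between -1.30 and -0.97 when each library was left out. Of 16 lists past the threshold, 8 kept side and direction in every refit: the axis, recombination, pachytene, spermatid, piRNA, Sertoli, mitotic and interferon lists. Calls ended with the GC offset for the Leydig, p53 and mitochondrial lists (camera adjusted p = 0.0618, 0.0615 and 0.0530). Without both libraries numbered 1 they ended for the macrophage, p53 and homologous recombination and checkpoint lists (camera adjusted p = 0.458, 0.141 and 0.458). In that fit the Leydig, myoid and epididymis lists also lost their calls, and camera pointed lower (adjusted p = 0.999, 0.939 and 0.609). With an estimated correlation, and with directional fry, 0 lists passed. X-linked genes kept their direction and side in the 14 refits that gave them a test. Over 1165 refits of 78 other genes, most of them named here, 855 kept direction and side, 239 lost a call, 60 gained one and 11 reversed.

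Counts of called genes depended on the setting. Without a low-count filter 992 genes were lower and 154 higher (557 and 46 by at least 2-fold), which tests more genes (35085). DESeq2 gave 721 and 56 (425 and 16), limma-voom 15 and 0 (13 and 0), and the GC offset 20 higher, 5 by at least 2-fold; the cause was not tested. Without both libraries numbered 1, a fit with fewer samples, 155 were lower. Leaving out each library in turn, also with fewer samples, gave 0 to 624 lower and 0 to 31 higher, and 0 to 438 and 0 to 18 by at least 2-fold.

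The replicate number as a block gave 21 lower and 0 higher (21 and 0 by at least 2-fold), with 605 higher and 1324 lower at an unadjusted p under 0.05, brought the cholesterol list past the threshold (camera adjusted p = 0.0480) and ended the call of the epididymis list (0.0882). Libraries of the same number correlated at -0.34, 0.12 and -0.28 after removal of the group means, which gave no sign of pairing by number. With 3 libraries per group these values cannot exclude a pairing.

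Most reversed results lay near 0. A list counts as reversed where the direction given by camera changed, even where its median kept its sign, as for Leydig cells. Stra8 had a log2 fold change of -5.12891e-05 with library size alone, -0.0170 with the GC offset, -0.17 without both libraries numbered 1 and -0.14 to 0.22 when each library was left out; Prdm9 had -0.0674 to 0.118. The epididymal genes Crisp1 and Cdh16 had -1.35 and -0.49 without both libraries numbered 1, and -0.79 to 4.51 and -0.13 to 3.22 when each library was left out, lowest without sKO library 1. Without both libraries numbered 1, list medians were 0.0252 for Leydig cells, -0.0270 for myoid cells, -0.15 for stroma, -0.0856 for endothelium, -0.33 for epididymis, 0.0217 for the 53BP1 pathway and 0.0246 for chromatin repressors. When each library was left out, medians lay between -0.12 and 0.23 for stroma, 0.0163 and 0.255 for endothelium, -0.56 and 0.11 for red blood cells, -0.0447 and 0.0388 for chromatin repressors and -0.99 and 0.29 for adipose tissue. The cause was not tested.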

Other observations

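Genes of the axoneme, the motile core of cilia and flagella, were examined as a family chosen after the values were seen, as were the genes named in these paragraphs. Of 95 tested members 85 had lower estimates in sKO, with a median log2 fold change of -0.60, and 20 were called lower by edgeR. No p-value is given for the family, because falls of axonemal genes prompted it and it shares Tekt1 and Tekt2 with the pachytene list. Cfap46, Dnah7a and Drc7 fell by 2.43, 2.55 and 2.63 on the log2 scale, and Dnah7a has close paralogs.

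The early meiotic genes Stra8, Meiosin and Prdm9 did not pass the test, although Meiosin belongs to the axis list and Prdm9 to the recombination list, which passed lower in sKO and hold the called genes Kash5 and Spo11. Stra8, an inducer of meiotic entry and a member of the differentiating spermatogonia list, stood at 133 ± 33.0 CPM in WT and 134 ± 9.57 CPM in sKO (SD, n = 3 each; edgeR adjusted p = 0.975), its partner Meiosin had a log2 fold change of 0.14 (edgeR adjusted p = 0.583), and Prdm9, which marks the sites of recombination, had one of 0.06 (edgeR adjusted p = 0.854). The sign of Stra8 and Prdm9 changed when single libraries were left out, and a p above the threshold does not show that levels were equal. Of 13 interferon-inducible GTPases 12 had higher estimates (median 0.61, camera adjusted p = 0.231 with an estimated correlation), as had 10 of 10 genes of antigen presentation (median 0.50, adjusted p = 0.231 with an estimated correlation). B2m, the light chain of MHC class I, stood at 68.4 ± 9.11 CPM in WT and 117 ± 28.5 CPM in sKO (SD, n = 3 each; edgeR adjusted p = 0.0548).

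The tests of spermatogonia, of dilution and of macrophages, and the count of epididymal genes detected in the other 5 libraries, were chosen only after the results were seen. For the lower pachytene genes, a lower share of all germ cells would lower spermatogonia genes too. But the 34 pooled genes had a median of 0.14 (SE 0.05, over genes), above the bound of -0.65 set for that explanation. Relative to the WT mean the undifferentiated list stood at 0.11, 0.18 and 0.16 in sKO libraries 1 to 3. The differentiating list stood at 0.10, 0.07 and 0.13. A GC bias between libraries is argued against by a list median of -1.34 (SE 0.30) after a GC offset. A difference in developmental stage between the animals, with fewer cells having reached pachytene, stays open. The difference of WT library 1 from WT library 2 correlated with that of WT library 3 from the sKO mean (r = 0.234 across genes). Across the 26 pachytene members r was 0.518. Genes are not independent, and such a correlation is not specific to stage. WT libraries 1 and 2 also differed in GC trend (-0.19 and 0.17 log2 per 10% GC) and in macrophage level (-0.33 and 0.22). An arrest or delay caused by the genotype may give the same pattern as a stage difference and was not tested apart from it.

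For the higher interferon genes, dilution by fewer germ cell transcripts is argued against, because the list exceeded the Sertoli list by 0.38 (SE 0.13, over genes). That SE leaves out the spread between samples. Relative to the WT mean the interferon list stood at 0.68, 0.39 and 0.65 in sKO libraries 1 to 3. The Sertoli list stood at 0.21, 0.29 and 0.11, so the 2 lists lay close in sKO library 2. The macrophage and myoid lists, with medians of 0.35 and 0.29, also exceeded the Sertoli list. The Sertoli list alone therefore does not bound a change in cell composition. With an estimated correlation, camera gave the interferon list an adjusted p of 0.426. A GC bias is also argued against, by a median of 0.56 (SE 0.12, over genes) after the offset. More macrophages are neither shown nor excluded by the list's excess of 0.24 (SE 0.15) over the macrophage list. Macrophage genes stood at 0.44, 0.45 and -0.01 relative to the WT mean in sKO libraries 1 to 3. They thus exceeded interferon genes in sKO library 2 (0.45 against 0.39) but not in sKO library 3 (-0.01 against 0.65). Without WT library 1 the medians were 0.08 for macrophages and 0.53 for interferon genes. A response to the genotype stays open and untested.

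For the epididymal genes of sKO library 1, a second list of epididymal genes, not examined before, had 7 of 14 detected members highest in that library against 2.33 expected by chance. With detection judged on the other 5 libraries it was 4 of 11, against 1.83 (one-sided exact binomial p = 0.00411 and 0.0956, which take the genes as independent, although genes of 1 tissue move together). Attached epididymal tissue stays a candidate explanation, and no biological explanation was tested. Without sKO library 1 the pachytene list still had a median of -1.26.

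The 6 libraries can be split in 10 ways, so the share of splits as large as the real one cannot fall under 0.1. The real split gave 240 genes lower and 6 higher, against at most 1 in any other split in either count, and it was 1 of 10 for each. By at least 2-fold it gave 182 and 3, against at most 1. It gave 16 lists past the threshold, against at most 15. For X-linked genes its -log10 p of 7.28 was exceeded by a split at 10.3, so 2 of the 10 splits were as large.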
